A study of Homo sapiens with 41 samples.

How the data were processed

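Total RNA libraries from 14 groups of a layered alveolar culture were compared, 7 groups from the apical and 7 from the basolateral compartment. Per the labels, RNA was purified with a QIAGEN kit and libraries were made from 1 µg of total RNA with the SMARTer Stranded Total RNA kit (HI Mammalian), and exposure lasted 24 h. The genome build was GRCh38.p13 per the submitters' processing notes, while the aligner, the read counter, the strand setting and the annotation are not given in the sources used here. The values are deposited read counts per gene, made by the authors as whole numbers and not normalized. Even numbers made up 67.7 to 78.9% of the low counts in each library, which would follow if both reads of a pair were counted, so that the counts may hold less information than their size. The table held 57773 genes, of which 29633 had no read in any library, and 90.6% of the gene identifiers stood in GENCODE 29, from which positions were taken. Of 530 genes in the fixed lists 529 were found, 10 of them under an older symbol by their identifier, and the endothelial marker PECAM1 was not.

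The apical libraries held 5243390 to 11660700 counts (median 8465710) and the basolateral libraries 2751300 to 10538100 (median 7910240). Between 15215 and 19051 genes had reads, and the 10 most abundant genes took 4.14 to 5.73% of a library. A floor of 3 counts came to 0.257 to 1.09 CPM. The median standard error of a log2 fold change was 0.172 to 0.207 over the comparisons with control. No 2 libraries of a group were copies of each other, and every column of the table belonged to a labelled sample.

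Each particle group was compared with the control of its compartment, then shapes with each other at the same number and 1000 with 500 within a shape. Genes were tested in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood F test in robust mode, TMM scaling, the filterByExpr filter and group as the only term, and called at a Benjamini-Hochberg adjusted p under 0.05. The p-values measure the spread between these samples, which the study's design text calls biological replicates. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the preset correlation of 0.01, adjusted over the lists with at least 3 members, and again with an estimated correlation. Marker levels are sums of CPM over a list in each library, whose exact permutation test cannot give a p under 0.1 with 3 against 3. Gene lists, tests, thresholds and the alternatives for apical spheres 1000 were fixed before the data were examined. The extension of the list tests and alternatives to the other comparisons, the fits with marker levels or library sets, the DESeq2 adjustment over all genes and the difference between compartments were added after.

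Genes were named by a rule fixed in advance. It took called genes with an average log2 CPM of at least 1 whose exposed and control libraries did not overlap, up to 10 in each direction, or, where none passed, the 5 with the smallest p in each direction. It added up to 4 members of each list by p and up to 3 markers by level. The text names part of these, and any other gene is given as chosen after its values were seen. Some genes that the rule names are not reported here. Copies with near-identical sequence, pseudogenes and readthrough transcripts are named as uncertain.

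Whether replicate numbers paired the libraries was checked from the deviations of each library from its group mean, before the fits with and without a block were compared. The numbers were taken as pairs where every same-numbered correlation was above 0.1. This held for apical spheres 1000 (0.531, 0.33 and 0.691 for replicates 1, 2 and 3) and apical rods 1000 (0.565, 0.268 and 0.717) against control and for basolateral stars 1000 against control (0.412, 0.274 and 0.5). Among direct comparisons it held for apical spheres 1000 against rods 1000 (0.584, 0.483 and 0.738), spheres 500 against rods 500 (0.543, 0.204 and 0.351) and stars 1000 against stars 500, and for basolateral spheres 1000 against stars 1000 and 1000 against 500 of rods and of stars. In spheres 500 against rods 500 not every library was closest to its own number.

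The test was tried on simulated data for apical spheres 1000 against control, with 14013 genes. With group only it recovered 3 of 67 genes raised or lowered 1.5-fold, 36 of 67 at 2-fold and 52 of 66 at 4-fold, with 11 false calls among 103, of which 1 was in a list of 25 other genes raised together 1.5-fold. With the replicate number as a block it recovered 28, 53 and 63, with 32 false calls among 192, of which 16 were in such a list. The raised list got an estimated-correlation p of 0.00142 with group only and 0.027 with the block, in limma's camera on simulated counts without adjustment. The simulated genes varied independently, so they cannot tell how that test does on lists whose genes vary together. Alternatives were RLE, upper quartile and no scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of CPM 5 in 3 libraries, a log2 fold change of at least 1, an adjusted p under 0.1, the block, each library left out, and all groups of a compartment in 1 fit, alone, with the block, with the mast (apical) or macrophage (basolateral) marker level, or with 3 sets of apical libraries by KIT level as a block. DESeq2's calls used its own filter on low means, and were also counted with the adjustment over all genes. Tables were read with the R package data.table, version 1.17.8. No sample was left out.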

Results

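Total RNA was sequenced from a layered culture model of the lung alveolus after 24 h with gold nanoparticles shaped as spheres, rods or stars, or with none (control). The apical compartment, at the air-liquid interface, held A549 cells, a lung adenocarcinoma line with features of alveolar epithelium, together with THP1 cells, a monocytic leukaemia line differentiated before use. The basolateral compartment, submerged, held the endothelial line labelled EA.hy296. Each shape came with the number 1000 or 500 in its sample title, whose unit the labels do not give. The 41 libraries fell into 14 groups, 7 per compartment, with 3 replicates in each group except basolateral spheres 500, which had replicates 1 and 3. Median counts were 8465710 apically and 7910240 basolaterally. The first principal component carried 29.8% of the variance between apical libraries and 50.6% between basolateral libraries. On it the apical libraries stood at -32.8 to -20.1 in the first, -16.1 to -2.83 in the second and 30.7 to 38.3 in the third of the library sets described below. The basolateral libraries stood at -64.4 to -17.4 in replicate 1 and -11.7 to 63.9 in replicate 3, where rods 1000 was the lowest. Levels are given as counts per 1000000 counts of the library (CPM), as mean ± SD over the replicates of a group (n = 3 unless stated), and log2 fold changes as estimate ± standard error.

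The apical libraries expressed epithelial, myeloid and mast cell genes side by side. KIT, the stem cell factor receptor that marks mast cells, ranged from 103 to 973 CPM over the 21 apical libraries, although no mast cell line stands in the sample labels. The labels name 3 cell lines in all, while the series title speaks of a tetra-culture. By KIT level the libraries parted into 3 sets of 7. The first set (KIT 760.0 to 973 CPM) held replicate 1 of every group. The second (KIT 444 to 513 CPM) held replicates 2 and 3 of spheres 500, and the third (KIT 103 to 138 CPM) those of rods 500. Every other group had 1 library in each set. Exchanged labels between a spheres 500 and a rods 500 library would give this, which was not tested. In the basolateral libraries ALDH1A1, an aldehyde dehydrogenase abundant in A549 cells, measured 1150.3, 644 and 139 CPM in control replicates 1, 2 and 3. In rods 1000 it measured 1181, 726 and 782 CPM.

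**Figure D1:**
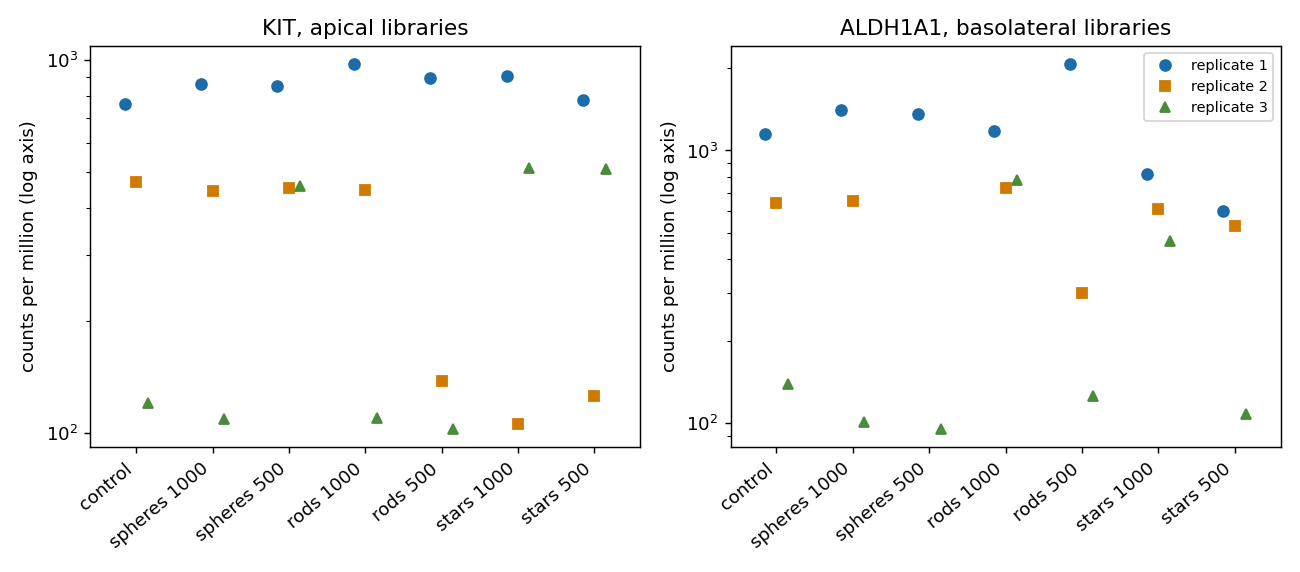
Levels (CPM, log axis) of KIT in the apical libraries (left) and ALDH1A1 in the basolateral libraries (right), by group, with a marker per replicate number. KIT stood between 760.0 and 973 CPM in replicate 1 of every apical group, while replicates 2 and 3 changed places between groups.

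The first comparison asked which apical transcripts respond to spheres 1000. The interferon response list stood higher than control in 25 of 25 members, with a median log2 fold change of 0.67 (adjusted p = 1.97e-21 in limma's camera with its preset correlation, but adjusted p = 0.44 with an estimated correlation). MX1, a dynamin-like GTPase that blocks the replication of RNA viruses (ENSG00000157601, chromosome 21, 41420304 to 41459214, GRCh38), measured 102 ± 33.1 against 48.5 ± 7.91 CPM, a log2 fold change of 1.09 ± 0.24, with 3 of 3 exposed libraries above every control library. IFIT3, which binds the antiviral adaptor MAVS, measured 101 ± 12.2 against 63.2 ± 14.3 CPM (0.69 ± 0.18). OASL, an oligoadenylate synthetase-like activator of RNA sensing, had a log2 fold change of 1.17 ± 0.31, IFI44, an interferon-induced protein of the cytoplasm, 1.63 ± 0.40, and TRIM22, an interferon-induced ubiquitin ligase, 0.91 ± 0.20. None of the 25 members passed an adjusted p of 0.05 over all genes, while 16 had an unadjusted p under 0.05 and 11 passed when adjusted over the list alone (MX1, adjusted p = 0.0281 in edgeR).

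The NF-κB cytokine list was likewise higher in 24 of 24 members in apical spheres 1000 (median log2 0.39, camera adjusted p = 7.38e-10; adjusted p = 0.758 with an estimated correlation). CXCL2, a neutrophil-attracting chemokine, measured 367 ± 31.3 against 276 ± 30.9 CPM (0.43 ± 0.12), and the related chemokine CXCL3 had a log2 fold change of 0.64 ± 0.18. The alarmin cytokine IL1A followed with 0.87 ± 0.30 and CCL20, a chemokine for dendritic cells and lymphocytes, with 0.80 ± 0.29. MMP1, the interstitial collagenase (ENSG00000196611, chromosome 11, 102789920 to 102798160), measured 33.3 ± 12.5 against 10.4 ± 5.25 CPM (1.66 ± 0.44), and stood at 1567 ± 207 CPM in basolateral control. In the same apical libraries CDH5, the cadherin of endothelial junctions, measured 12.5 ± 3.95 against 4.35 ± 3.21 CPM, and 821 ± 165 CPM in basolateral control. The list of cytoskeleton, mesenchymal transition and matrix genes had 15 of 21 members above control (median log2 0.18, adjusted p = 0.0165; adjusted p = 0.758 with an estimated correlation). The immediate early list had 12 of 16 above control (median log2 0.24, adjusted p = 0.016; adjusted p = 0.44 with an estimated correlation), with IER3, a stress-induced survival gene, at 0.34 ± 0.12. SLC39A10, a zinc importer, was lower at 132 ± 25 against 191 ± 17.2 CPM (-0.51 ± 0.14) and was the 1 member of the metal list to pass when adjusted over the list alone (adjusted p = 0.0354 in edgeR).

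**Figure D2:**
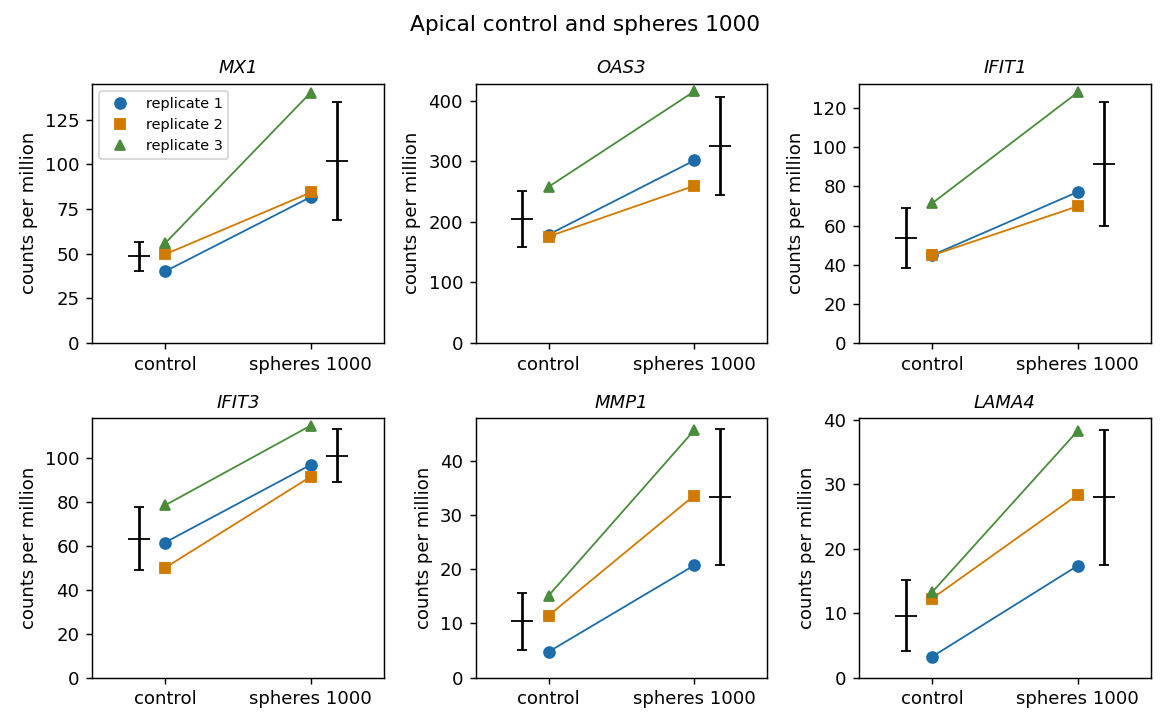
Levels in CPM of 6 genes in the 3 apical control and the 3 apical spheres 1000 libraries; lines join libraries with the same replicate number and the bars show mean ± SD. MX1 rose from a control mean of 48.5 to 102 CPM in the fit with the replicate number as a block, and every exposed library lay above every control library in MX1, IFIT3 and MMP1.

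Same-numbered apical control and spheres 1000 libraries deviated together, and with the replicate number as a block edgeR called 27 genes, 24 higher and 3 lower. MX1 rose by 1.06 ± 0.12 on the log2 scale (adjusted p = 0.000547 in edgeR with the block) and MMP1 by 1.71 ± 0.17 (adjusted p = 0.000322). The interferon genes OAS3, which makes the activator of RNase L, IFIT1, which binds foreign RNA ends, and IFI44L, a relative of IFI44, rose by 0.68 ± 0.09, 0.78 ± 0.10 and 1.41 ± 0.24 (adjusted p = 0.0021, 0.00219 and 0.0204). LAMA4, a laminin chain of vessel walls, rose by 1.60 ± 0.21 and PODXL, a sialomucin of endothelium, by 0.76 ± 0.13. These last 5 genes were chosen after their values were seen. Carried-over endothelial RNA was not tested as a source of LAMA4, PODXL or MMP1. By list, 5 of the calls were interferon genes, 2 matrix genes and 8 mitochondrially encoded genes, and 12 were in no list. Of these 12, 3 were nuclear copies of mitochondrial sequence (MTRNR2L genes), whose reads cannot be assigned with certainty. With all apical groups in 1 fit and the library set as a block, edgeR called 0 genes here (805 at an unadjusted p under 0.05), and no other tool was run with that block. Without any block the log2 fold change was 0.47 for IFIT1 and 0.40 for PODXL without spheres 1000 replicate 3.

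Endothelial markers were higher in apical spheres 1000 in 11 of 12 tested members (median log2 0.61, camera adjusted p = 6.35e-06; adjusted p = 0.44 with an estimated correlation), although the compartment was seeded with no endothelial line, and their summed level was 89.1 ± 11.4 against 62.5 ± 8.1 CPM. The 13 mitochondrially encoded genes stood higher (median log2 0.74, adjusted p = 2.1e-12; adjusted p = 0.627 with an estimated correlation) and summed to 20673 ± 4746 against 12891 ± 5517 CPM. The ribosomal protein genes stood lower in 19 of 19 (median log2 -0.11, adjusted p = 0.00296; adjusted p = 0.758 with an estimated correlation). The remaining lists were not called. Their median log2 fold changes, each with its camera adjusted p, were for stress and death metallothionein and zinc transport 0.24 (0.432), NRF2 oxidative stress -0.01 (0.679), unfolded protein response -0.05 (0.432), heat shock 0.05 (0.316), p53 target 0.08 (0.198), proliferation 0.07 (0.141), cell death and inflammasome 0.12 (0.177) and hypoxia 0.05 (0.228). For metabolism, uptake and barrier they were acute phase and complement 0.06 (0.432), cholesterol synthesis 0.04 (0.432), fatty acid -0.07 (0.244), lysosome -0.06 (0.339), endocytosis -0.02 (0.494), tight junction 0.03 (0.749) and xenobiotic 0.02 (0.491). For cell markers and RNA class they were alveolar epithelial marker -0.07 (0.491), macrophage marker -0.05 (0.491), dendritic marker -0.15 (0.141), mast cell marker 0.09 (0.986) and non-polyadenylated RNA -0.19 (0.228), where the mast cell list had a positive median and mean but a negative direction in its test. With all apical groups in 1 fit and the library set as a block, the medians were 0.70 for interferon genes, 0.46 for NF-κB cytokines and 0.14 for matrix genes (camera adjusted p = 0.0853 for the last). The fibroblast markers, too few for the list test, summed to 5.23 ± 1.48 against 6.62 ± 1.1 CPM.

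Without the block, edgeR called 0 of 14013 genes in this comparison. At an unadjusted p under 0.05 there were 254, DESeq2 called 4, limma-voom 0 and edgeR with no filter on low counts 2. DESeq2's calls included MX1 (adjusted p = 0.0299) and 2 loci with near-identical relatives, whose reads are uncertain. RGPD1, a nucleoporin-like gene, was at 5.52 ± 5.44 CPM and 0 in control, and the unnamed locus RP11-512M8.5 at 0 and 7.65 ± 2.73 CPM in control. The calls of the interferon, NF-κB, endothelial and mitochondrial lists held in each of the 6 fits that left out 1 library. The immediate early call was lost without control replicate 2 or 3 or spheres 1000 replicate 2 (adjusted p up to 0.179), the ribosomal call without control replicate 1 or spheres 1000 replicate 1 or 3, and the matrix call without control replicate 1 or spheres 1000 replicate 3 (up to 0.94). The immediate early (adjusted p = 0.108) and matrix (0.3) calls were lost with no filter on low counts and the matrix (0.0565, median 0.15) call with the mast cell marker covariate.

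Spheres 500 asked the same question at the lower number. In the apical compartment the NF-κB cytokine list lay below control in 22 of 24 members (median log2 -0.45, camera adjusted p = 0.000346; adjusted p = 0.721 with an estimated correlation). Within it PTGS2, the inducible cyclooxygenase, measured 1634 ± 452 against 2451 ± 337 CPM (-0.61 ± 0.22). EGFR, the epidermal growth factor receptor, measured 270.0 ± 17.3 against 376 ± 46.7 CPM (-0.50 ± 0.11), and TANC2, a postsynaptic scaffold, had a log2 fold change of -0.35 ± 0.08, while F2RL1, a protease-activated receptor, was higher at 0.49 ± 0.12. The complement component C3 (-0.37 ± 0.12), CHAC1, which degrades glutathione (-1.30 ± 0.45), and ITGA2, a collagen-binding integrin (-0.32 ± 0.12), all stood lower. The log2 fold change was -0.40 for PTGS2 without spheres 500 replicate 1 and -0.24 for C3 without control replicate 3. The proliferation list was above control in 23 of 25 members (median log2 0.16, adjusted p = 0.000454), the endothelial markers in 12 of 13 (0.90, 5.07e-06), the mast cell markers in 8 of 8 (0.42, 0.0498), the mitochondrially encoded genes at 0.20 (0.0296) and the ribosomal protein genes at 0.09 (0.0264). Cell death (-0.17, 0.0264), cholesterol synthesis (-0.07, 0.0396) and dendritic marker lists (-0.30, 0.0498) lay below it, and with an estimated correlation the adjusted p was 0.788 for mast cell markers, 0.835 for mitochondrial genes and 0.721 for the others. In single genes edgeR called 0 of 14124 genes, with 458 at an unadjusted p under 0.05, 2 called by DESeq2, 0 by limma-voom and 2 by edgeR with no filter on low counts. The 2 in DESeq2 were SMIM3, a small membrane protein, at 4.55 ± 2.43 CPM and 0 in control, and the numbered locus KIAA0391_2, a copy of a mitochondrial RNase P gene, at 0 and 7.35 ± 3.69 CPM in control. By edgeR, 0 list members passed when adjusted over the list alone. Only the endothelial call held in all 6 fits that left out 1 library. Without control replicate 3 the other 8 were lost (adjusted p up to 0.857), 6 without control replicate 2, 5 without spheres 500 replicate 1, 1 without replicate 2 and 2 without replicate 3. Without control replicate 1 edgeR called 1 gene. This group had no library of the third set. With the library set as a block over all apical groups, the medians were -0.12 for NF-κB cytokines (camera adjusted p = 0.071), 0.03 for proliferation (0.209), 0.02 for mast cell markers (0.874) and -0.07 for dendritic markers (0.539). In that fit endothelial markers (1.04, 9.67e-12; 0.431 estimated) and mitochondrially encoded genes (0.24, 0.0077; 0.979 estimated) stayed called. There the interferon median was 0.30 (0.013; 0.979 estimated). The dendritic (adjusted p = 0.0515) call was lost with RLE scaling, the cell death (0.0684), cholesterol (0.0755), dendritic (0.0755), mast cell (0.0755), mitochondrial (0.0663) and ribosomal (0.0755) calls with no filter on low counts, the proliferation (0.0508, median 0.10), cell death (0.345, -0.04), cholesterol (0.135, -0.05), dendritic (0.345, -0.11), mast cell (0.919, -0.01) and ribosomal (0.481, 0.05) calls with the mast cell marker covariate and the cell death (0.539, median -0.02), cholesterol (0.502, -0.04) and ribosomal (0.958, 0.00) calls with the library set as a block. The NF-κB median was -0.18 with the mast cell marker covariate, which, like the sets by KIT, largely fixes the mast cell result.

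In apical rods 1000, TMSB10, a thymosin that sequesters actin monomers (ENSG00000034510, chromosome 2, 84905625 to 84906675), fell to 589.5 ± 24.4 against 824 ± 7.09 CPM (-0.49 ± 0.08, adjusted p = 0.00581 in DESeq2, and 0.0156 in edgeR with the replicate number as a block). RPS27A, which encodes a ubiquitin fusion with a ribosomal protein and has processed pseudogenes that may take up its reads, measured 555 ± 26.1 against 767 ± 93.6 CPM (-0.47 ± 0.11). It passed with the block (adjusted p = 0.0388 in edgeR) and, without it, when adjusted over the list alone (adjusted p = 0.0354). GAS5, a growth-arrest noncoding RNA that hosts small nucleolar RNAs, measured 95.5 ± 25.6 against 179.9 ± 61.4 CPM and fell with the block (-0.90 ± 0.09, adjusted p = 0.00419), as did CHGB, a granin of secretory granules (-0.49 ± 0.07, adjusted p = 0.024). Both were named after their values were seen, and the same-numbered libraries of this comparison deviated together. With the block edgeR called 5 genes, and 0 with the library set as a block over all apical groups (695 at an unadjusted p under 0.05), where no other tool was run. Without the block the log2 fold change was -0.61 for GAS5 and -0.24 for CHGB without control replicate 1, -0.75 for CHGB without rods 1000 replicate 1 and -0.29 for CHGB without rods 1000 replicate 2. MYCT1, a target of the MYC oncogene, was higher at 2.35 ± 0.59. FABP5, a fatty acid carrier (-0.42 ± 0.13), XBP1, a transcription factor of secretory stress (-0.29 ± 0.11), and SCAMP3, a membrane protein of the secretory route (-0.44 ± 0.11), were lower.

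Among the lists in apical rods 1000, proliferation stood above control in 24 of 25 members (median log2 0.22, camera adjusted p = 4.16e-07; adjusted p = 0.948 with an estimated correlation), endothelial markers in 11 of 12 (0.75, 3.44e-05; 0.722 estimated) and interferon response genes in 23 of 25 (0.31, 0.00226; 0.961 estimated). Immediate early genes had a median of 0.17 (0.0243; 0.548 estimated), cholesterol synthesis -0.08 (0.0243; 0.948 estimated) and fatty acid genes -0.10 (0.0243; 0.548 estimated). With the replicate number as a block the fatty acid list was not called (camera adjusted p = 0.0694) and the NRF2 oxidative stress list was (median log2 0.11 without the block, adjusted p = 0.0262 with it; adjusted p = 0.935 with an estimated correlation). Without the block edgeR called 0 of 14206 genes, with 215 at an unadjusted p under 0.05, 4 called by DESeq2, 0 by limma-voom and 0 by edgeR with no filter on low counts. Of the list members, 1 passed in edgeR when adjusted over the list alone. The proliferation and endothelial calls held in all 6 fits that left out 1 library, and the others were lost without 1 or more of the 3 control and 3 rods 1000 libraries, most often without control replicate 2 (4 calls), with adjusted p up to 0.564 without rods 1000 replicate 2. The immediate early (adjusted p = 0.135), cholesterol (0.151) and fatty acid (0.151) calls were lost with no filter on low counts.

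Apical rods 500 had interferon response genes above control in 25 of 25 members (median log2 0.74, camera adjusted p = 2.57e-09; adjusted p = 0.853 with an estimated correlation). ISG15, a ubiquitin-like modifier, measured 17.5 ± 3.64 against 8.84 ± 1.11 CPM (1.02 ± 0.24), and XAF1, a pro-apoptotic interferon target, 0.74 ± 0.25 on the log2 scale. Macrophage markers stood higher in 22 of 24 (0.36, 9.37e-07; 0.572 estimated), as did SLA, an adaptor of immune receptor signalling, at 56.5 ± 5.45 against 38.1 ± 1.89 CPM (0.59 ± 0.13), and FERMT3, a kindlin of blood cells (0.43 ± 0.12). Endothelial markers (12 of 12, 0.98, 1.95e-07; 0.572 estimated) and PGF, a placental growth factor for vessels (1.78 ± 0.48), were higher too. The lists of hypoxia (20 of 20, 0.20, 7.3e-05; 0.806 estimated), matrix (18 of 22, 0.46, 0.00485; 0.853 estimated) and mitochondrially encoded genes (13 of 13, 0.21, 0.00517; 0.853 estimated) were also called. FN1, the matrix glycoprotein fibronectin, was lower nonetheless at 2895 ± 167 against 4501 ± 1311 CPM (-0.61 ± 0.21). JUN, a component of the AP-1 transcription factor (0.48 ± 0.16), and PPP1R15A, which restores translation after stress (0.45 ± 0.16), were higher. Of 14020 genes tested one by one, edgeR called 0, with 240 at an unadjusted p under 0.05, 0 called by DESeq2, 0 by limma-voom and 0 by edgeR with no filter on low counts. Adjusted over the list alone, 0 list members passed in edgeR. The interferon, macrophage, endothelial and hypoxia calls held in all 6 fits that left out 1 library. The matrix call was lost without control replicate 1 or rods 500 replicate 2 or 3 (adjusted p up to 0.336 without control replicate 1) and the mitochondrial call without control replicate 3 (0.986) or rods 500 replicate 3. This group had no library of the second set. With the library set as a block over all apical groups, the medians were 0.49 for interferon genes (camera adjusted p = 0.000215; 0.768 estimated), 0.24 for macrophage markers (7.39e-06; 0.471 estimated), 0.86 for endothelial markers (3.62e-08; 0.471 estimated) and 0.21 for matrix genes (0.517). The matrix call was lost with no filter on low counts (adjusted p = 0.14) and with the mast cell marker covariate (0.151, median 0.23). With that covariate the hypoxia median was 0.11 and the mitochondrial median 0.33. With the library set as a block the hypoxia median was 0.12.

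In apical stars 1000, ANXA8, a calcium-dependent membrane-binding annexin with near-identical copies, fell to 3.6 ± 0.281 against 13.2 ± 4.64 CPM (-1.88 ± 0.33, adjusted p = 0.019 in DESeq2). The protein-coding locus RP11-73M18.2, of no established function, rose to 31.6 ± 5.97 against 14.1 ± 1.14 CPM (1.16 ± 0.18, adjusted p = 0.00833 in DESeq2). CSF3, the granulocyte colony-stimulating factor, measured 11 ± 0.513 against 31.5 ± 17.6 CPM (-1.53 ± 0.41), KIAA1199, a hyaluronan-degrading protein, 55.5 ± 14.2 against 105 ± 22 CPM (-0.92 ± 0.22), and PTGS2 -0.47 ± 0.16 on the log2 scale. HHIP, an antagonist of hedgehog ligands (-0.37 ± 0.10), and LRP1, an endocytic receptor (-0.49 ± 0.17), were lower, and TUBA1C, an alpha tubulin, higher (0.33 ± 0.10). Without control replicate 1 LRP1 was at -0.28. Proliferation genes stood above control in 23 of 25 members (median log2 0.23, camera adjusted p = 6.48e-06; adjusted p = 0.999 with an estimated correlation) and immediate early genes in 15 of 16 (0.18, 0.0266; 0.754 estimated). Endothelial markers were above it in 12 of 13 (0.45, 0.000301; 0.754 estimated) and ribosomal protein genes in 17 of 19 (0.10, 0.0366; 0.999 estimated). Cholesterol synthesis genes lay below it in 20 of 21 (-0.11, 0.013; 0.999 estimated), and dendritic markers at -0.32 (0.0366; 0.999 estimated). In the test of 14004 single genes edgeR called 0, with 243 at an unadjusted p under 0.05, 4 called by DESeq2, 0 by limma-voom and 3 by edgeR with no filter on low counts. By edgeR, 0 list members passed when adjusted over the list alone. Each of the 6 list calls was lost in at least 1 of the fits that left out 1 library, 5 of them without control replicate 3 (adjusted p up to 0.781), 5 without stars 1000 replicate 3, 3 without control replicate 2 or stars 1000 replicate 1, and the endothelial call without control replicate 1. The cholesterol (adjusted p = 0.112), dendritic (0.671) and ribosomal (0.0852) calls were lost with no filter on low counts, the dendritic (0.193, median -0.36) and ribosomal (0.0524, 0.11) calls with the mast cell marker covariate and the dendritic (0.174, median -0.34) call with the library set as a block.

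In apical stars 500 the NF-κB cytokine list lay below control in 24 of 24 members (median log2 -0.40, camera adjusted p = 1.93e-06; adjusted p = 0.847 with an estimated correlation), and cholesterol synthesis genes in 20 of 21 (-0.13, 9.54e-05; 0.839 estimated). Proliferation genes stood above it in 25 of 25 (0.21, 6.14e-06; 0.847 estimated) and heat shock genes in 12 of 13 (0.14, 0.00372; 0.839 estimated). Endothelial markers had a median of 0.24 (0.0297; 0.847 estimated) and dendritic markers of -0.30 (0.0219; 0.847 estimated). TMC5, a transmembrane channel-like protein of epithelia, measured 55.1 ± 1.82 against 74.5 ± 9.09 CPM (-0.42 ± 0.13), and TFEB, the transcription factor of lysosomal genes, 5.11 ± 0.647 against 9.34 ± 2.77 CPM (-0.86 ± 0.30, or -0.57 without control replicate 3). PARP2, a DNA repair polymerase (0.44 ± 0.15), and ZNF721, a zinc finger protein (0.50 ± 0.15), were higher. For single genes edgeR called 0 of 14075 genes, with 156 at an unadjusted p under 0.05, 2 called by DESeq2, 0 by limma-voom and 0 by edgeR with no filter on low counts. Those 2 were RGPD1 (4.51 ± 3.95 CPM) and SMIM3, both at 0 in control. Of the list members, 0 passed in edgeR when adjusted over the list alone. Each list call was lost in at least 1 of the 6 fits that left out 1 library, 4 without stars 500 replicate 1, 4 without replicate 3, 2 without control replicate 3 and the endothelial call without control replicate 1 (adjusted p = 0.891). The dendritic call was lost with no filter on low counts (adjusted p = 0.287) and with the mast cell marker covariate (0.0562, median -0.57). The dendritic median was -0.61 with the library set as a block.

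**Figure D3:**
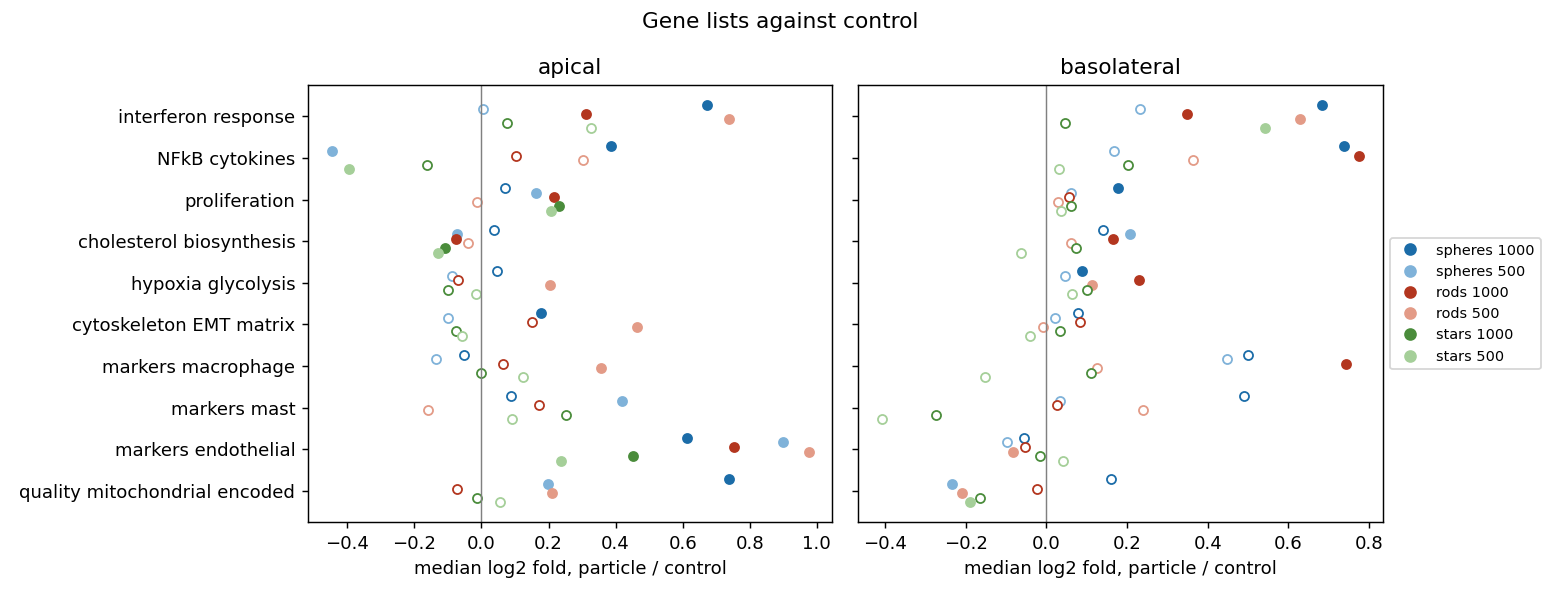
Median log2 fold change against control of the members of 10 gene lists in the apical (left) and basolateral (right) libraries, 1 point per particle group; filled points had a camera adjusted p under 0.05 with the preset correlation, and with an estimated correlation none did. The interferon list ran from 0.00 in apical spheres 500 to 0.74 in apical rods 500 (0.30 and 0.49 with the library set as a block over all apical groups), and the 6 comparisons of a compartment share 1 control group.

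The basolateral comparisons asked whether the endothelial layer beneath responded. With spheres 1000 the NF-κB cytokine list stood above control in 25 of 25 members (median log2 0.74, camera adjusted p = 2.57e-06; adjusted p = 0.883 with an estimated correlation) and the interferon list in 24 of 24 (0.68, 2.03e-16; 0.883 estimated). In the same libraries the macrophage markers had a median of 0.50 (camera adjusted p = 0.557) and summed to 346 ± 306 against 261 ± 163 CPM, and the mast cell markers had a median of 0.49 (0.875). Spheres 1000 replicate 2, the shallowest library of the series (2751300 counts), lay at 58.3 on PC2 and the other basolateral libraries at -12.2 to 6.09. With the macrophage marker level as a covariate over all basolateral groups the medians were 0.66 for NF-κB cytokines (0.000825; 0.842 estimated) and 0.73 for interferon genes (1.7e-16; 0.842 estimated). IL8, the main neutrophil chemokine, measured 349 ± 241 against 121 ± 43.7 CPM (1.53 ± 0.54, or 0.81 without spheres 1000 replicate 1), and CSF2, the granulocyte-macrophage growth factor, had a log2 fold change of 1.52 ± 0.51 (0.98 without spheres 1000 replicate 3). ISG15 (0.84 ± 0.30), IFI44 (0.69 ± 0.25) and GBP1, an interferon-induced GTPase (0.76 ± 0.25), were higher. MMP10, the stromelysin that activates other matrix proteases, measured 231 ± 101 against 109.7 ± 12.9 CPM (1.07 ± 0.33, or 0.71 without spheres 1000 replicate 1). EDN1, the precursor of the vasoconstrictor endothelin, was lower at 37.4 ± 2.89 against 58.7 ± 2.37 CPM (-0.67 ± 0.12), as was UACA, an apoptosis regulator (-0.49 ± 0.11), while IL7R, a cytokine receptor (1.13 ± 0.27), and SERPINB2, a serpin of stressed cells (1.26 ± 0.35), were higher. Proliferation (0.18, 0.00238; 0.883 estimated) and hypoxia genes (0.09, 0.00822; 0.883 estimated) had smaller medians. Of 13081 genes tested one by one, edgeR called 0, with 195 at an unadjusted p under 0.05, 2 called by DESeq2, 0 by limma-voom and 0 by edgeR with no filter on low counts. Adjusted over the list alone, 0 list members passed in edgeR. The interferon call held in all 6 fits that left out 1 library. The NF-κB call was lost without spheres 1000 replicate 1, with the proliferation and hypoxia calls (adjusted p up to 0.303), and those 2 also without control replicate 3 (up to 0.907). The hypoxia (adjusted p = 0.0764) call was lost with no filter on low counts.

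Basolateral spheres 500 had 2 libraries against 3. SULT1A4, a sulfotransferase with a near-identical copy whose reads it may share, measured 8.69 ± 0.0481 against 18.9 ± 0.27 CPM (-1.12 ± 0.16). MYZAP, a myocardial zonula adherens protein that also occurs in a readthrough transcript, fell to 0.352 ± 0.0897 against 9.14 ± 6.66 CPM (-4.64 ± 0.91, adjusted p = 0.0224 in DESeq2). TENM1, a transmembrane teneurin (-0.53 ± 0.13), was lower and PPP4C, a protein phosphatase (0.40 ± 0.11), higher. Cholesterol synthesis genes stood above control in 19 of 21 members (median log2 0.21, camera adjusted p = 0.0092; adjusted p = 0.985 with an estimated correlation), and mitochondrially encoded genes below it in 13 of 13 (-0.23, 0.0092; 0.985 estimated). In the test of 13659 single genes edgeR called 0, with 130 at an unadjusted p under 0.05, 2 called by DESeq2, 0 by limma-voom and 0 by edgeR with no filter on low counts. By edgeR, 0 list members passed when adjusted over the list alone. Both list calls were lost without control replicate 3 (adjusted p up to 0.528), the cholesterol call without spheres 500 replicate 1 (0.646), and the mitochondrial call without control replicate 1 (0.195) or spheres 500 replicate 3 (0.642). The macrophage markers had a median of 0.45 (0.892). The mitochondrial (adjusted p = 0.0801, median -0.30) call was lost with the macrophage marker covariate. Its median was -0.44 with the replicate block, where the numbers did not pair the libraries.

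In basolateral rods 1000, MMP10 (ENSG00000166670, chromosome 11, 102770503 to 102780628) rose to 220.1 ± 7.99 against 109.7 ± 12.9 CPM (0.98 ± 0.13), with 3 of 3 exposed libraries above every control library (adjusted p = 1.79e-07 in DESeq2, 0.236 in edgeR, 1.03e-06 in edgeR with no filter on low counts). The NF-κB cytokine list stood above control in 25 of 25 members (median log2 0.78, camera adjusted p = 1.54e-09; adjusted p = 0.787 with an estimated correlation). IL1B, a pyrogenic inflammasome product (ENSG00000125538, chromosome 2, 112829751 to 112836903), measured 34 ± 12.4 against 10.5 ± 5.13 CPM (1.69 ± 0.44). IL8 measured 394 ± 208 against 121 ± 43.7 CPM (1.69 ± 0.48) and CXCL2 73.3 ± 18.9 against 37 ± 7.29 CPM (0.97 ± 0.21). Of the list members, 3 passed in edgeR when adjusted over the list alone, MMP10 (adjusted p = 0.000355), CXCL2 (0.0285) and TGFBI, a matrix protein induced by TGF-beta (0.51 ± 0.12, 0.0152). MX1 measured 11.2 ± 2.59 against 3.82 ± 1.8 CPM (1.54 ± 0.38). GFPT2, an enzyme of the hexosamine route (0.56 ± 0.11), SERPINE2, a protease nexin (0.65 ± 0.14), and SQSTM1, an autophagy receptor (0.47 ± 0.16), were higher, and UACA (-0.50 ± 0.12), GIMAP4, a GTPase of immune and endothelial cells (-0.77 ± 0.15), and CGNL1, a junctional protein (-0.49 ± 0.12), lower.

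Further lists were above control in basolateral rods 1000. Interferon response genes were so in 22 of 24 members (median log2 0.35, camera adjusted p = 7.53e-05; adjusted p = 0.787 with an estimated correlation) and macrophage markers in 20 of 20 (0.74, 6.71e-06; 0.787 estimated), in a compartment seeded with no macrophages. With the macrophage marker level as a covariate over all basolateral groups, the median of macrophage markers was -0.04 (camera adjusted p = 0.855). Their own level largely fixes this. The medians of NF-κB cytokines and interferon genes were 1.01 (1.96e-06, 0.913 estimated) and 0.77 (1.05e-09, 0.597 estimated). Acute phase genes (11 of 12, 0.69, 0.00578), NRF2 targets (18 of 20, 0.18, 0.00689), hypoxia genes (0.23, 0.00689), xenobiotic genes (0.46, 0.00429) and cholesterol synthesis genes (0.16, 0.00689; 0.794 estimated) followed, the first 4 at 0.787 with an estimated correlation. With that covariate their medians were -0.13 (0.418), -0.04 (0.855), 0.20 (0.0765), -0.06 (0.532) and 0.02 (0.855). For single genes edgeR called 0 of 13301 genes, with 396 at an unadjusted p under 0.05, 1 called by DESeq2, 0 by limma-voom and 7 by edgeR with no filter on low counts. The NF-κB and macrophage calls held in all 6 fits that left out 1 library. Without control replicate 3, 5 of the others were lost (adjusted p up to 0.9), 4 without rods 1000 replicate 1, 3 without replicate 3. The interferon call was also lost without control replicate 2 and the hypoxia call without control replicate 1 or rods 1000 replicate 2.

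**Figure D4:**
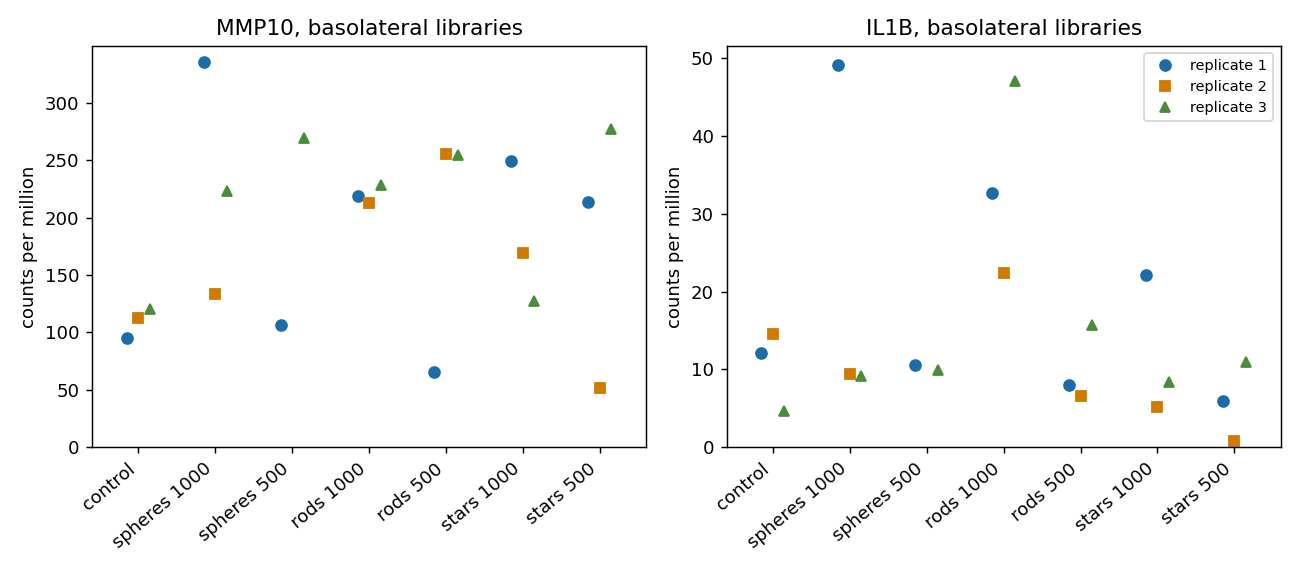
Levels in CPM of MMP10 (left) and IL1B (right) in each basolateral library, by group, with a marker per replicate number. The 3 rods 1000 libraries lay above the 3 control libraries in both genes, with means of 220.1 and 34 CPM against 109.7 and 10.5.

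In basolateral rods 500 interferon response genes stood above control in 24 of 24 members (median log2 0.63, camera adjusted p = 7.52e-05; adjusted p = 0.983 with an estimated correlation). Hypoxia genes (0.11, 0.0295; 0.983 estimated) were higher, and endothelial markers (14 of 17, -0.08, 0.0187; 0.983 estimated) and mitochondrially encoded genes (13 of 13, -0.21, 0.0102; 0.983 estimated) lower. DUSP16, a phosphatase of stress kinases, measured 35.6 ± 3.4 against 24.1 ± 4.58 CPM (0.56 ± 0.15). SLC16A7, a pyruvate transporter (-0.58 ± 0.16), and PNPLA2, a triglyceride lipase (-0.48 ± 0.14), were lower, and DNAJB9, a chaperone of the endoplasmic reticulum, higher (0.35 ± 0.13). Of 13210 genes tested one by one, edgeR called 0, with 141 at an unadjusted p under 0.05, 1 called by DESeq2, 0 by limma-voom and 0 by edgeR with no filter on low counts. Of the list members, 0 passed in edgeR when adjusted over the list alone. Each list call was lost in at least 1 of the 6 fits that left out 1 library. The interferon call was lost without control replicate 2 or rods 500 replicate 3 (adjusted p = 0.0593 without the former), the endothelial call without rods 500 replicate 1 (0.984) or control replicate 3, and the hypoxia and mitochondrial calls without control replicate 1 or 3 or rods 500 replicate 2. The hypoxia call was also lost without rods 500 replicate 3. The hypoxia (adjusted p = 0.134), endothelial (0.0917) and mitochondrial (0.0509) calls were lost with no filter on low counts and the hypoxia (0.0571, median 0.10), endothelial (0.0571, -0.08) and mitochondrial (0.15, -0.22) calls with the macrophage marker covariate. With that covariate the interferon median was 0.56 (2.31e-09; 0.92 estimated).

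In basolateral stars 1000, KITLG, the ligand of the KIT receptor, measured 510.1 ± 29.1 against 378 ± 47.6 CPM (0.42 ± 0.13). NRIP3, a nuclear receptor interactor, measured 33.4 ± 2.91 against 21.6 ± 1.84 CPM (0.62 ± 0.13). S1PR3, a sphingosine phosphate receptor (0.71 ± 0.19), and MMP10 (0.71 ± 0.23, or 0.43 without stars 1000 replicate 1) were higher, and CCDC112, a centriolar satellite protein, lower at 55.6 ± 7.67 against 84.8 ± 8.25 CPM (-0.62 ± 0.12). No list was called by camera, where the lowest adjusted p with an estimated correlation was 0.99. With the replicate number as a block, where same-numbered libraries deviated together, cholesterol synthesis genes (median log2 0.07 without the block) and mitochondrially encoded genes (-0.17) were called (camera adjusted p = 0.0397 and 0.000754; adjusted p = 0.988 for both with an estimated correlation). In the test of 13182 single genes edgeR called 0, with 211 at an unadjusted p under 0.05, 1 called by DESeq2, 0 by limma-voom and 0 by edgeR with no filter on low counts. Adjusted over the list alone, 0 list members passed in edgeR. With 1 library left out, 1 to 8 lists were called, the highest count without control replicate 2.

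In basolateral stars 500 interferon response genes stood above control in 23 of 24 members (median log2 0.54, camera adjusted p = 0.0123; adjusted p = 0.942 with an estimated correlation). NRF2 targets lay below it in 19 of 20 (-0.18, 0.0203; 0.942 estimated), and mitochondrially encoded genes had a median of -0.19 (0.0322; 0.942 estimated). In the same libraries alveolar epithelial markers had a median of -0.58 (camera adjusted p = 0.128), acute phase genes -0.94 (0.0559), mast cell markers -0.41 (0.563) and macrophage markers -0.15 (0.563), and ALDH1A1 measured 412 ± 265 against 644 ± 506 CPM. Between the control groups the NRF2 targets were higher in the apical compartment (median log2 1.63, camera adjusted p = 1.81e-06; adjusted p = 0.545 with an estimated correlation). NRIP3 measured 30.7 ± 1.68 against 21.6 ± 1.84 CPM (0.51 ± 0.13), and SPATA18, a p53 target of mitochondrial quality control, 12.4 ± 0.463 against 7.73 ± 1.21 CPM (0.69 ± 0.19). SMOX, spermine oxidase (-0.53 ± 0.15), SYNGR2, a vesicle protein (-0.42 ± 0.09), and EGR1, an immediate early transcription factor near the detection floor (-1.35 ± 0.51), were lower. For single genes edgeR called 0 of 13030 genes, with 165 at an unadjusted p under 0.05, 0 called by DESeq2, 0 by limma-voom and 0 by edgeR with no filter on low counts. By edgeR, 0 list members passed when adjusted over the list alone. Each list call was lost in at least 1 of the 6 fits that left out 1 library. This was so for the interferon call without control replicate 2 or stars 500 replicate 3, the NRF2 call without those or control replicate 1 or stars 500 replicate 2, and the mitochondrial call without control replicate 1 or 3 or stars 500 replicate 1 or 2 (adjusted p up to 0.957 without the last). The NRF2 (adjusted p = 0.122) and mitochondrial (0.122) calls were lost with no filter on low counts and the mitochondrial (0.195, median -0.13) call with the macrophage marker covariate.

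Particles were also compared directly, shape against shape at the same number and 1000 against 500 within a shape. In apical spheres 1000 against rods 1000, whose same-numbered libraries deviated together, edgeR with the replicate number as a block called 42 genes, 35 higher with spheres and 7 lower. GAS5 measured 214 ± 68.9 against 95.5 ± 25.6 CPM (blocked log2 1.18 ± 0.08, adjusted p = 1.02e-06) and SNHG1, another host of small nucleolar RNAs, had a log2 fold change of 1.42 ± 0.11. KIAA1199 (1.05 ± 0.08), TMSB10 (0.47 ± 0.08), FTH1, the ferritin heavy chain (0.37 ± 0.07), SLC39A8, a zinc and manganese importer (0.43 ± 0.08), and the mitochondrially encoded MT-ND3 (0.95 ± 0.14) were also called. Of the 42, 4 were in a fixed list. With the library set as a block over all apical groups edgeR called 1 gene (1132 at an unadjusted p under 0.05). Without any block the log2 fold change was 0.58 for KIAA1199 without spheres 1000 replicate 1 and 0.23 for SLC39A8 without rods 1000 replicate 2.

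In apical spheres 500 against rods 500, where pairs 2 and 3 also differed in library set, the block gave 76 calls, 76 of them lower with spheres. MMP14, a membrane-bound matrix protease, measured 71.9 ± 35.7 against 200.2 ± 118 CPM (blocked log2 -1.46 ± 0.13, adjusted p = 0.00914), and IL1B 102 ± 70.4 against 234 ± 143 CPM (-1.33 ± 0.12). The calls took in 11 of 24 NF-κB genes, among them the superoxide dismutase SOD2 (-0.92 ± 0.10), the adhesion molecule ICAM1 (-0.96 ± 0.11), IL8 (-1.02 ± 0.12), the NF-κB inhibitor TNFAIP3 (-0.98 ± 0.12) and the monocyte chemokine CCL2 (-1.01 ± 0.15). They also held 4 of 25 macrophage markers, among them the growth factor receptor CSF1R (-1.03 ± 0.14) and the leukocyte phosphatase PTPRC (-0.77 ± 0.10), and the tryptophan-degrading enzyme IDO1 (-2.41 ± 0.28). Without the block the log2 fold change was -0.77 for IL1B, -0.62 for SOD2, -0.51 for IL8, -0.61 for TNFAIP3, -0.51 for PTPRC and -0.51 for CCL2 without spheres 500 replicate 1 and -0.63 for ICAM1 and -0.42 for CCL2 without rods 500 replicate 3. Pairs 2 and 3 cannot tell shape from library set. With the set as a block over all apical groups edgeR called 0 genes (531 at an unadjusted p under 0.05), and the median log2 difference was -0.03 for NF-κB cytokines (camera adjusted p = 0.208), -0.02 for interferon genes (0.308) and -0.21 for macrophage markers (3.42e-06; 0.333 estimated).

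Other direct calls came from DESeq2. Apical spheres 1000 against stars 1000 gave 26, with CSF3 at 68.3 ± 43.4 against 11 ± 0.513 CPM (2.65 ± 0.45, adjusted p = 1.99e-09 in DESeq2), IL6, a cytokine of the acute phase (1.71 ± 0.42), and MUC5AC, a gel-forming mucin (1.04 ± 0.26), higher with spheres. Adjusted over all genes with a p, DESeq2 called 23, without IL6 (adjusted p = 0.0508). There edgeR with the library set as a block over all apical groups called 8 genes (1855 at an unadjusted p under 0.05). Apical spheres 1000 against spheres 500 gave 17, with PTGS2 (0.99 ± 0.26, adjusted p = 0.00477 in DESeq2), EGFR (0.64 ± 0.18) and BIRC3, an inhibitor of apoptosis (0.86 ± 0.29), higher at 1000. DESeq2's own filter left 1170 of 23389 genes with an adjusted p here. Adjusted over all 23389 it called 9, of which 1 was among the 17, PTGS2 (adjusted p = 0.0159, against 0.243 for EGFR and 0.183 for BIRC3). Without spheres 1000 replicate 3 EGFR was at 0.41. Spheres 500 had 1 library of the first set and 2 of the second, and spheres 1000 had 1 of each of the 3, and with the set as a block edgeR called 0 genes (834 at an unadjusted p under 0.05), where no other tool was run. Basolateral rods 1000 against rods 500 gave 3, with IL23A, a subunit of interleukin 23 (2.56 ± 0.53, adjusted p = 0.000869 in DESeq2), and CXCL1, a neutrophil chemokine (1.44 ± 0.42, or 0.90 without rods 1000 replicate 3), higher at 1000. The genes named in the direct comparisons were chosen after their values were seen. In all 18 direct comparisons edgeR without the block called 0 genes, with 53 to 793 at an unadjusted p under 0.05, 85 calls by DESeq2, 2 by limma-voom and 61 by edgeR with no filter on low counts. Leaving out apical rods 500 replicate 1, the 1 library of that group in the first set, gave 904 calls in edgeR for spheres 500 against rods 500. Leaving out basolateral rods 500 replicate 1 gave 109 for rods 1000 against rods 500. Leaving out apical rods 1000 replicate 2, apical spheres 1000 replicate 1, basolateral spheres 1000 replicate 2 or basolateral stars 500 replicate 1 gave 1 call each in 1 comparison.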

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

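All tests in this part were chosen after the data were seen. Each result is a gene list whose response to a particle differed between the 2 compartments in the interaction term of limma's camera with its preset correlation, and is given as the apical against the basolateral median log2 fold change. None was called with an estimated correlation, and the adjusted p of that test stands second beside each. The endothelial markers differed with 5 particles, in spheres 1000 (0.61 against -0.06, adjusted p = 1.4e-07, adjusted p = 0.391 estimated), spheres 500 (0.90 against -0.10, adjusted p = 1.32e-06, adjusted p = 0.852 estimated), rods 1000 (0.75 against -0.05, adjusted p = 5.6e-05, adjusted p = 0.858 estimated), rods 500 (0.98 against -0.08, adjusted p = 3.14e-10, adjusted p = 0.169 estimated) and stars 1000 (0.45 against -0.02, adjusted p = 0.00300, adjusted p = 0.989 estimated). CDH5 measured 4.35 ± 3.21 CPM in apical control and 8.94 to 17.3 CPM in the means of the apical particle groups. It measured 821 ± 165 CPM in basolateral control. The mitochondrially encoded genes differed in spheres 1000 (0.74 against 0.16, adjusted p = 2.65e-05, adjusted p = 0.995 estimated), spheres 500 (0.20 against -0.23, adjusted p = 0.000297, adjusted p = 0.852 estimated) and rods 500 (0.21 against -0.21, adjusted p = 0.000175, adjusted p = 0.965 estimated). The NF-κB cytokines differed in spheres 500 (-0.45 against 0.17, adjusted p = 0.000284, adjusted p = 0.852 estimated) and rods 1000 (0.10 against 0.78, adjusted p = 0.000258, adjusted p = 0.858 estimated), and the cholesterol synthesis genes in spheres 500 (-0.07 against 0.21, adjusted p = 0.000143, adjusted p = 0.852 estimated), rods 1000 (-0.08 against 0.16, adjusted p = 0.00112, adjusted p = 0.858 estimated) and stars 1000 (-0.11 against 0.07, adjusted p = 0.00300, adjusted p = 0.989 estimated). With the library set as a block over all apical groups the apical spheres 500 median was -0.12 for NF-κB cytokines (camera adjusted p = 0.071 against control) and -0.04 for cholesterol synthesis genes (0.502).

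In rods 1000 further lists differed between the compartments, acute phase genes (-0.09 against 0.69, adjusted p = 0.00205, adjusted p = 0.858 estimated), proliferation genes (0.22 against 0.06, adjusted p = 0.0201, adjusted p = 0.941 estimated), fatty acid genes (-0.10 against 0.08, adjusted p = 0.0194, adjusted p = 0.858 estimated), hypoxia genes (-0.07 against 0.23, adjusted p = 0.0194, adjusted p = 0.858 estimated), xenobiotic genes (0.00 against 0.46, adjusted p = 0.0194, adjusted p = 0.858 estimated), macrophage markers (0.06 against 0.74, adjusted p = 0.000530, adjusted p = 0.858 estimated) and dendritic markers (-0.22 against 0.67, adjusted p = 0.0194, adjusted p = 0.858 estimated). With the macrophage marker level as a covariate over all basolateral groups, the basolateral medians in rods 1000 were -0.13 for acute phase genes. They were -0.07 for proliferation, -0.13 for fatty acid, 0.20 for hypoxia, -0.06 for xenobiotic and 0.02 for cholesterol synthesis genes. They were 1.01 for NF-κB cytokines and 0.07 each for dendritic and endothelial markers. The matrix genes differed in rods 500 (0.46 against -0.01, adjusted p = 0.00522, adjusted p = 0.965 estimated), with an apical median of 0.21 with the library set as a block (camera adjusted p = 0.517 against control), and the ribosomal protein genes in stars 1000 (0.10 against -0.05, adjusted p = 0.00909, adjusted p = 0.989 estimated). In stars 500 no list was called (lowest adjusted p = 0.969 with an estimated correlation). Among single genes edgeR called 0 for each of the 6 particles, with 291, 299, 489, 320, 409 and 344 at an unadjusted p under 0.05 in the same order, and no other tool was run. No biological explanation was tested for these differences.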

How the results depend on the processing

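Chosen after the data were seen were the alternatives for every comparison but apical spheres 1000 against control, and for that comparison the DESeq2 adjustment over all genes and the fits with marker levels, library sets or the block in the fit of all apical groups. Counts of 0 called genes against control stayed at 0 with RLE, upper quartile or no scaling, limma-voom, the filter on CPM, a fold threshold, an adjusted p under 0.1 and all groups in 1 fit, alone or with the block, the marker level or the library set. DESeq2 called 4 in apical spheres 1000, 2 in spheres 500, 4 in rods 1000, 4 in stars 1000 and 2 in stars 500, and in basolateral libraries 2 in spheres 1000, 2 in spheres 500 and 1 each in rods 1000, rods 500 and stars 1000, and the same numbers when adjusted over all genes. With no filter edgeR called 2 each in apical spheres 1000 and spheres 500, 3 in apical stars 1000 and 7 in basolateral rods 1000. With the replicate block it called 27 in apical spheres 1000 and 5 in apical rods 1000, where the numbers paired the libraries, and 1 each in apical rods 500 and basolateral spheres 500, where they shared only a number. The block changed no other count of genes against control. For lists it changed no call in apical spheres 1000, changed the calls given for apical rods 1000 and basolateral stars 1000, and changed others where the numbers did not pair the libraries. The fry test called no list in any comparison with control (lowest adjusted p = 0.211). Without apical control replicate 1 spheres 500 had 1 call, so that its counts ran from 0 to 1. Summed over the 18 direct comparisons, where the main count was 0, the counts were 2 with limma-voom, 85 with DESeq2, 74 with DESeq2 adjusted over all genes, 61 with no filter, 207 with the replicate block, 9 with the library set in 1 fit (over the 9 apical of the 18) and 2 at an adjusted p under 0.1, and leaving out 1 library gave 0 to 904 (904 without apical rods 500 replicate 1, in spheres 500 against rods 500, and 109 without basolateral rods 500 replicate 1, in rods 1000 against rods 500). For the lists of apical spheres 1000 against control, 7 were called, 7 to 10 with 1 library left out, and 0 with an estimated correlation (alone, or with the block, the marker level or the library set) or with the fry test. The tight junction list, not called in any of these, turned its direction with no filter (adjusted p = 0.482 in limma's camera), with the marker level (0.603, or 0.783 with an estimated correlation) and with the library set (0.748 and 0.829). The mast cell list did so with the marker level (0.854 and 0.851) and the library set (0.892 and 0.903). With 1 library left out the direction turned in 15 lists, none called in the fit of all libraries, whose adjusted p ran over unfolded protein response 0.109 to 0.733, NRF2 0.0559 to 0.998, cholesterol 0.0238 to 0.998, endocytosis 0.19 to 0.828, heat shock 0.0173 to 0.993, hypoxia 0.0299 to 0.998, lysosome 0.11 to 0.993, alveolar epithelial 0.362 to 0.886, dendritic 0.000967 to 0.886, macrophage 0.12 to 0.841, mast cell 0.0362 to 0.982, proliferation 0.000967 to 0.841, non-polyadenylated 0.0117 to 0.998, tight junction 0.362 to 0.982 and xenobiotic 0.214 to 0.998. The 126 named gene results kept direction in all 1256 alternatives (RLE, DESeq2, no filter, block, each library left out). In 71 they passed the threshold only there (35 block, 23 DESeq2). Choosing them in these data partly fixed this outcome. The log2 ratios of marker and quality sums in apical spheres 1000 over control moved by less than 1 SD between replicates with TMM scaling, as list medians or with 1 library left out. Even so, with 1 library left out they ran from -0.62 to 0.58 for mast cell, -0.27 to 0.25 for dendritic, -0.39 to 0.03 for alveolar epithelial and -0.44 to 0.03 for non-polyadenylated genes, so that no direction was fixed for these. The cause of these changes was not tested. Depth limits genes near the floor of 3 counts, and no alternative planned in advance was left out.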

Other observations

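All tests of this part were chosen after the data were seen. The apical and basolateral control libraries differed in 3791 genes higher and 3894 lower in the apical compartment of 14198 tested by edgeR. CDH5 measured 4.35 ± 3.21 CPM in apical and 821 ± 165 CPM in basolateral control (log2 -7.62 ± 0.61) and CAV1, the coat protein of caveolae, 45.5 ± 10.4 CPM in apical and 1165 ± 179.9 CPM in basolateral control (log2 -4.81 ± 0.26). THBS1, a matrix glycoprotein, measured 109 ± 41.6 CPM in apical and 5898 ± 1047 CPM in basolateral control (log2 -5.89 ± 0.40) and MMP1 10.4 ± 5.25 CPM in apical and 1567 ± 207 CPM in basolateral control (log2 -7.33 ± 0.48). The endothelial list stood lower in the apical compartment (median log2 -6.73, adjusted p = 4.25e-09, 17 of 17 members called in edgeR, adjusted p = 0.543 estimated). The list values are from limma's camera with the preset correlation, then an estimated one. The p53 target list stood lower as well (median log2 -1.61, adjusted p = 4.91e-06, 17 of 21 members called in edgeR, adjusted p = 0.545 estimated), with MDM2, which degrades p53, at 373 ± 28.5 CPM in apical and 1124 ± 104 CPM in basolateral control (log2 -1.74 ± 0.14).

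Higher in the apical compartment were KRT8, a keratin of simple epithelia (2495 ± 87.6 CPM in apical and 330.2 ± 196 CPM in basolateral control, log2 2.79 ± 0.46), and LYZ, the lysozyme of myeloid cells (487 ± 34.3 CPM in apical and 50.5 ± 35.8 CPM in basolateral control, 3.14 ± 0.69). So were NQO1, a quinone reductase (1280.3 ± 169 CPM in apical and 249.9 ± 65.5 CPM in basolateral control, 2.22 ± 0.20) and C3 (847 ± 109 CPM in apical and 42.4 ± 29.1 CPM in basolateral control, 4.20 ± 0.71). By list these included macrophage markers (median log2 3.33, camera adjusted p = 1.81e-06, 22 of 22 members called in edgeR) and NRF2 targets (1.63, 1.81e-06, 19 of 20). Cholesterol synthesis (adjusted p = 3.08e-07, 20 of 21), acute phase genes (3.77, 0.000139, 11 of 14) and xenobiotic genes (3.14, 0.0166, 10 of 14) followed. So did NF-κB cytokines (2.66, 0.00172, 19 of 25, with 4 called lower). Each had a camera adjusted p = 0.545 estimated. With an estimated correlation camera called none of the lists in this comparison.

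KIT varied 9.48-fold between apical libraries, and the other mast cell markers HDC, TPSAB1, CPA3 and GATA2 varied with it. A varying share of mast cell RNA is a candidate explanation. The SD of the log2 ratio to KIT was 0.473 in the median of 8 other markers against 1.25 for KIT itself over 21 libraries, although SLC18A2, an amine transporter on the same list, followed KIT with a slope of only 0.276 in log2. The sample labels name no mast cells, while the series title speaks of a tetra-culture. A changed state of the THP1 cells stays open, as macrophage markers varied 1.38-fold, and no other biological explanation was tested.

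Of apically abundant genes, 108 low basolaterally were chosen in spheres 500 libraries, which may lower their shares and favour 1 ratio. They stood in basolateral libraries at a median of 14, 7.76 and 0.797% of their apical level in control replicates 1, 2 and 3. RNA of apical cells in 1 ratio may be their source but stays open, since 99.1% of them lay within 2-fold of that median in replicates 1 and 2 and 78.7% in replicate 3, where KIT, ALDH1A1 and LYZ stood at 1.45, 1.92 and 2.19% (13.3, 14.4 and 17.7% in replicate 1). Expression by the basolateral line was excluded in replicate 1 only as sole source. There the myeloid and mast genes KIT, HDC, LYZ and TYROBP had 1.22 times the share of the A549 genes ALDH1A1 and AKR1B10. This was the median of 7 libraries (0.924 to 1.63). Reads misassigned from all apical libraries of the pool were excluded for replicate 3 alone, where the ratio of KIT to ALDH1A1 was -1.55 and -2.46 log2 from that of the pool in the 2 libraries tested. Such reads in replicates 1 and 2, where 1 of 13 libraries lay over 2-fold from the pool (12 of all 15 were closer to apical libraries of their number, at a median of 0.398 against 0.626 log2), and reads from apical libraries of the same number cannot be told apart from carried-over cells, and no other biological explanation was tested.

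The interferon response list stood 0.688 log2 above control in its mean in apical spheres 1000. A higher mitochondrial share and a differing share of mast cell RNA were excluded as the whole cause, as the median log2 fold change was 0.734 and 0.704 with these as covariates and 0.672 without. Low values in the shared control libraries stay open, since the list lay 0.464 log2 above the 15 libraries of the other apical particle groups, with an exact permutation p of 0.0741 over the 216 regroupings within library sets. A response to spheres 1000 may underlie the list, and remains a hypothesis. The mitochondrially encoded genes lay 0.662 log2 above those 15 libraries (exact permutation p = 0.00463, the smallest that these regroupings can give).

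Other splits of the libraries were counted for the 26 comparisons of 3 against 3, where the 10 splits are too few for a share under 0.05. The real split gave 0 calls in edgeR in each. The highest other split gave 2642 calls in apical rods 500 against stars 500, 2397 in apical rods 1000 against rods 500 and 1696 in apical rods 500 against control. It gave 680 in basolateral rods 500 against control, 169 in apical spheres 1000 against stars 1000 and 145 in apical spheres 1000 against rods 1000, and from 0 to 27 elsewhere (10 in apical spheres 1000 against control). Such counts point to a structure of the samples, and in the first 3 of these comparisons the split put libraries of the third KIT set apart from those of the first and second.

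With the preset correlation, the real split called in the apical compartment 7 lists with a highest other of 15 and 5 splits as large for spheres 1000, 9 lists with a highest other of 10 and 3 splits as large for spheres 500 and 6 lists with a highest other of 13 and 5 splits as large for rods 1000. It called 6 lists with a highest other of 12 and 6 splits as large for rods 500, 6 lists with a highest other of 16 and 5 splits as large for stars 1000 and 6 lists with a highest other of 16 and 6 splits as large for stars 500. In the basolateral compartment it called 4 lists with a highest other of 13 and 9 splits as large for spheres 1000 and 8 lists with a highest other of 12 and 7 splits as large for rods 1000. There it also called 4 lists with a highest other of 13 and 9 splits as large for rods 500, 0 lists with a highest other of 13 and 10 splits as large for stars 1000 and 3 lists with a highest other of 15 and 10 splits as large for stars 500. With the replicate number as a block, the 4 splits that part every pair are also too few for a share under 0.05. The real split gave 27 calls against at most 1 in another in apical spheres 1000 against control and 5 calls against at most 4 in another in rods 1000 against control. It gave 42 against at most 0 in spheres 1000 against rods 1000 and 76 against at most 0 in spheres 500 against rods 500. In each, 1 of 4 splits was as large. The other 3 mix the 2 groups on each side, and in the last, pairs 2 and 3 also differ in library set.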
